A study of Homo sapiens with 8 samples.

How the data were processed

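RNA of A375P melanoma cells was measured on 8 Affymetrix arrays for human genes, read in 1 colour, 2 for each of 4 lentiviral hairpins: shGFP and shScr as controls, and hairpins 65 and 66 against PGC1α. Total RNA was purified on columns, reverse transcribed from a T7 oligo-dT primer and transcribed in vitro into biotin-labelled cRNA. The deposited values are intensity values of 22277 probe sets on a linear scale, which the authors made with RMA (version not stated) and normalized across the arrays. The log2 was taken before every test, and folds come from means of log2 values, so they differ from the ratio of the printed mean signals where an arm is uneven. The array image files were not used here, and no detection calls came with the values, so whether a low value is background is unknown.

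Gene symbols came from the probe table of the array and were checked against the human RefSeq gene table of assembly GRCh38.p14; 0 symbols changed. Of the probe sets, 19070 had 1 symbol, 1043 several and 2164 none, and 62 were array control probe sets. For each of 11963 genes, the probe set with the highest mean signal was used, without a filter on signal.

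The 4 arrays with PGC1α hairpins were compared with the 4 with control hairpins in a 2-group limma fit (limma 3.58.1, R 4.3.3), whose residual spread, with 6 degrees of freedom, holds the differences between hairpins of an arm. Each hairpin against the controls, hairpin 65 against hairpin 66, and shGFP against shScr came from a 4-group fit with 4 degrees of freedom. P-values were adjusted by Benjamini and Hochberg over all genes, with a threshold of 0.05, and "rose" and "fell" refer to genes past it. PPARGC1A, and the 3′ minus 5′ difference of the ACTB and GAPDH control probe sets, were tested by an exact two-sided permutation of 4 against 4 arrays, whose smallest p is 0.0286. The labels do not say whether the 2 arrays of a hairpin come from separate cultures, so p-values measure only the spread between these samples, part of which may be technical.

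Before the data were examined, 22 gene lists were written: OXPHOS complex I, OXPHOS complexes II to V with cytochrome c, TCA cycle and pyruvate dehydrogenase, fatty acid oxidation, mitochondrial ribosome, PGC1 family and mitochondrial transcription, oxidant defence, glycolysis, hypoxia response, melanocyte lineage, invasive melanoma with integrins and extracellular matrix, p53 targets, cell cycle, MAPK output, interferon response, ATF4 and unfolded protein response, cholesterol synthesis, inflammatory and NF-kB targets, RNA interference machinery, and epithelial, fibroblast and blood markers. Of their 605 members, 520 were measured. Lists were tested with camera at a preset correlation of 0.01 and adjusted over the 22 lists; an estimated correlation and fry were alternatives. Another 6 lists (peroxisome, heme and iron-sulphur cluster, mitochondrial protein import, cytosolic ribosome, lysosome, BMP response) were written after the first results and were tested apart.

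The rule for named genes was also fixed before the data were examined. It takes PPARGC1A and the 8 largest rises and 8 largest falls among called genes whose arms do not overlap. From each list it takes the 2 called members with the smallest p (1 where there was only 1). Between the controls, between hairpins 65 and 66, and for both hairpins, it takes the 4 largest rises and falls among called genes. Between hairpins 65 and 66 no gene was called, so the 4 with the smallest p are named instead, a choice the rule did not set. Of the genes the rule takes, 1 is not reported here. Other genes are named after their values were seen. Of the 63 genes the rule takes, NDUFA5 and DICER1 have probe sets that differ in sign, 2 in all. Probe sets were compared, and alternatives run gene by gene, only for genes the rule takes.

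The fits were tested on simulated data with 11963 genes in 10 runs. In each run 200 genes were changed by known folds. A further short list of genes was lowered slightly, and its calls do not count as false. The 2-group fit recovered 76.2% of genes changed 1.25-fold and 98.8% of those changed 1.5-fold, with 5.31% false calls; with added hairpin effects these were 65.8%, 96.4% and 14.5%. For hairpin 65 against the controls, false calls were 5.26% of the calls without and 25.7% with hairpin effects. Far fewer genes were changed in the simulations than were called in the data, so these shares need not hold for the data.

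Alternatives were another probe set summary, a signal filter, cyclic loess and quantile normalization, a trend and robust variance, probe sets of suffix s_at or x_at left out, a replicate block, each array or hairpin left out, a fold minimum, hairpin as a random block, averaged arrays, and all probe sets tested singly. Added after seeing the data were the ACTB difference as a covariate, an estimated correlation in the 4-group fit, a crossed replicate block and other pairings of the arrays.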

Results

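Gene expression was measured on 8 arrays of A375P, a human melanoma cell line. Stable lines carried a lentiviral short hairpin RNA against PGC1α (hairpin 65 or hairpin 66) or a control hairpin (shGFP, or shScr, which the sample titles call shRNA-control). PGC1α, encoded by PPARGC1A, is a transcriptional coactivator that drives mitochondrial biogenesis. Cells were selected with puromycin for 48 h and RNA was taken 48 h later, with 2 arrays for each of the 4 hairpins. The median signal per array lay between 137 and 142, and the number of arrays limits the precision.

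The first comparison asked how far the hairpins lowered their target. PPARGC1A (Entrez gene 10891) had a signal of 556 ± 11.7 (SD, n = 4) in the control arrays and 125 ± 13.9 (SD, n = 4) in the arrays with PGC1α hairpins, a level 4.48-fold lower, or 22.3% of control (exact permutation p = 0.0286, two-sided, the smallest that 4 against 4 arrays allow). Its mean was 135 with hairpin 65 and 114 with hairpin 66. With limma, PPARGC1A fell by 2.05 on the log2 scale with hairpin 65 (adjusted p = 3.48e-06) and fell by 2.28 with hairpin 66 (adjusted p = 2.23e-06). Between the controls the signals were 551 with shGFP and 561 with shScr, a log2 difference of -0.02 (SE 0.07, adjusted p = 0.891).

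The RNA quality probe sets differed between the arms. For ACTB, the 3′ probe set exceeded the 5′ probe set by a log2 difference of 2.19 ± 0.18 (SD, n = 4) in the controls and 2.53 ± 0.11 (SD, n = 4) with the PGC1α hairpins, and the arms did not overlap (difference 0.35, exact permutation p = 0.0286). For GAPDH the same measure was 0.17 in the controls and 0.18 in the knockdown (exact permutation p = 0.571).

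**Figure D1:**
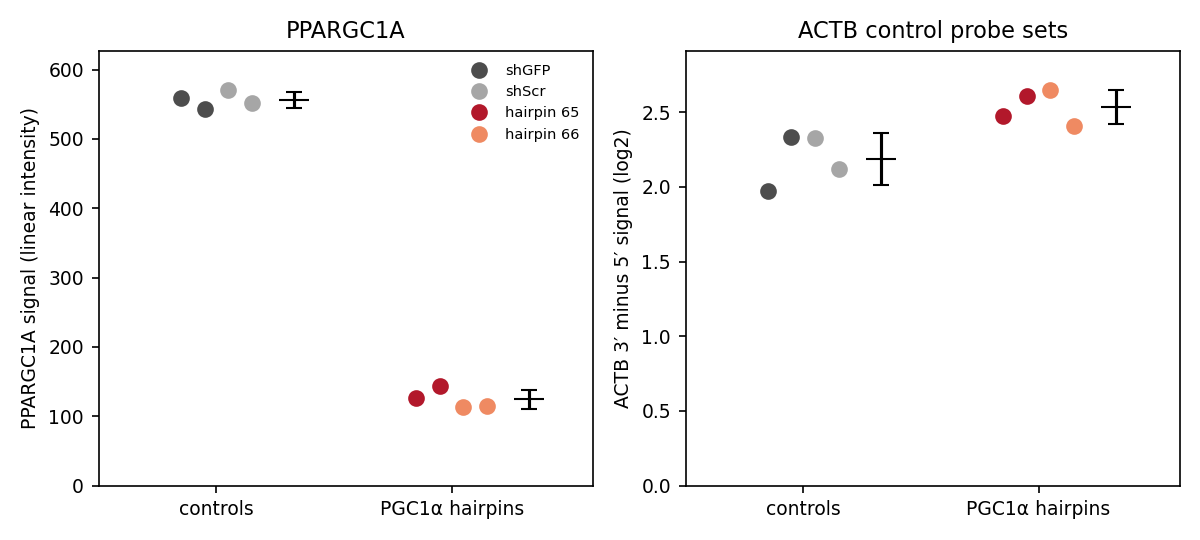
Each point is 1 array, coloured by hairpin, and the bars give the mean and SD of the 4 arrays of an arm. Left, PPARGC1A signal (linear intensity), 556 on average in the controls and 125 with the PGC1α hairpins; right, ACTB 3′ minus 5′ signal (log2), 1.97 to 2.34 in the controls and 2.41 to 2.65 with the PGC1α hairpins.

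The main comparison asked which genes differ between cells with PGC1α hairpins and cells with control hairpins. The largest rise was that of CEMIP, a hyaluronan-binding protein that promotes hyaluronan breakdown, from 234 ± 162 to 4466 ± 264 (SD, n = 4 in each arm), 23.8-fold by the means of log2 values (log2 SE 0.46, adjusted p = 1.07e-04). IL11, a cytokine, rose 12.9-fold, from 46.8 ± 15.6 to 579 ± 43.8 (adjusted p = 3.31e-06). INHBA, which encodes a subunit of activin A, rose 8.70-fold, from 207 ± 52.3 to 1761 ± 102 (adjusted p = 2.13e-06). The secreted BMP antagonist CHRDL1 (7.72-fold), the secreted glycoprotein OLFML3 (7.59-fold), the potassium channel KCNMA1 (7.34-fold), the secreted Wnt antagonist SFRP1 (6.87-fold) and the actin-binding coronin CORO2B (5.44-fold) rose as well. Of these 8 genes, CORO2B alone did not pass the test between the control hairpins (adjusted p = 0.170); the other 7 were lower in shGFP than in shScr, CHRDL1 by 2.08-fold and CEMIP by 3.98-fold. The 3 KCNMA1 probe sets ranged in log2 change from 0.01 to 2.88, the 2 of IL11 from 0.57 to 3.68 and the 2 of INHBA from 0.78 to 3.12.

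Among the declines, the cytokine IL24 went from 7454 ± 1479 to 947 ± 50.1 (SD, n = 4 in each arm), 7.76-fold lower (log2 SE 0.13, adjusted p = 1.11e-06). GALNT3, an enzyme that starts mucin-type O-glycosylation, was 5.81-fold lower with the probe set used, and its 2 probe sets ranged in log2 change from -2.54 to -0.10. ID2, an inhibitor of basic helix-loop-helix transcription factors, was 3.99-fold lower (426 to 106, adjusted p = 2.46e-05). CA8, a carbonic anhydrase-related protein, was 3.62-fold lower, ASPA, which cleaves N-acetylaspartate, 3.61-fold lower and the phosphatase gene PPM1H 3.36-fold lower. IL24 (1.41-fold), GALNT3 (1.59-fold), CA8 (1.55-fold), ASPA (1.45-fold) and PPM1H (1.85-fold) were also higher in shGFP than in shScr, with adjusted p from 3.14e-04 for PPM1H to 0.0171 for GALNT3. DKK1, a secreted Wnt antagonist, was 5.33-fold lower (adjusted p = 0.0331), and its control arrays stood apart, at 364 with shGFP and 45.3 with shScr. Leaving out either shGFP array or any 1 of the 4 knockdown arrays ended the DKK1 call, as did the replicate block (adjusted p = 0.0510) and a trend and robust variance (0.0915). Adjusted p was 0.0745 (without shGFP replicate 1), 0.077 (shGFP replicate 2), 0.0653 and 0.0888 (hairpin 65 replicates 1 and 2), 0.0762 and 0.0647 (hairpin 66 replicates 1 and 2), in a range of 1.03e-05 to 0.563 over 14 alternatives.

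Across all 11963 genes, limma called 1384 higher and 1275 lower with the PGC1α hairpins, 2659 in all or 22.2%, of which 348 rose and 204 fell at least 1.5-fold. The 4 knockdown arrays all lay outside the 4 control arrays in 3287 of all 11963 genes. Chance gives 2.86% of genes only if the 8 arrays are independent. They come in 2 per hairpin, and 939 genes differed between the control hairpins, so the share by chance may be higher by an unknown amount. The count of called genes was 1387 without hairpin 65, 1467 without hairpin 66, 878 with the 2 arrays of each hairpin averaged, 1601 without probe sets of suffix s_at or x_at, and 3989 with all probe sets tested singly. With the ACTB difference as a covariate, an alternative chosen after seeing the data, 529 genes passed; 512 of the 2659 kept their call, 0 changed sign, and at the median the log2 changes of the called genes were 0.956 times as large and their standard errors grew 1.77-fold.

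Lists of mitochondrial enzymes and ribosomal proteins were lower with the PGC1α hairpins with the preset correlation, and 0 of the lists passed with an estimated one. Of the 64 measured subunit genes of oxidative phosphorylation (OXPHOS), 38 fell and 0 rose, 61 had a negative change, and the median change was -13.4%. In the list of complex I, 14 of 28 fell and 0 rose (16 and 0 adjusted over the list alone), with a median log2 change of -0.18 (list adjusted p = 7.72e-06, and adjusted p = 0.251 with an estimated correlation). Its strongest calls were NDUFA5, 2.05-fold lower (3093 to 1514, adjusted p = 1.99e-05), and NDUFA3, 1.40-fold lower; a second NDUFA5 probe set gave a log2 change of 0.06. In complexes II to V with cytochrome c, 24 of 36 fell and 0 rose (28 and 0 adjusted over the list alone), with a median of -0.25 (list adjusted p = 1.37e-12, and adjusted p = 0.208 with an estimated correlation). The complex III core subunits UQCRC2 and UQCRC1 were 1.53-fold and 1.36-fold lower. The arms that these lists compare also differed in the ACTB 3′ over 5′ difference, which was 0.35 higher in the knockdown arrays.

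For the tricarboxylic acid (TCA) cycle and pyruvate dehydrogenase, 11 of 19 measured genes fell and 0 rose (13 and 0 adjusted over the list alone), with a median log2 change of -0.27 (list adjusted p = 2.40e-07, and adjusted p = 0.105 with an estimated correlation). Citrate synthase (CS) was 1.37-fold lower and the pyruvate dehydrogenase subunit PDHA1 1.36-fold lower; SDHA and SDHD, which fell, stand in this list and in the second OXPHOS list. In fatty acid oxidation, 9 of 19 fell and 0 rose (14 and 0 adjusted over the list alone), with a median of -0.20 (list adjusted p = 4.58e-06, and adjusted p = 0.225 with an estimated correlation). ECI1, an isomerase for unsaturated fatty acids, was 1.56-fold lower and ETFDH, which passes electrons from acyl-CoA dehydrogenases to ubiquinone, 1.44-fold lower. The mitochondrial ribosome had 17 of 49 genes lower, among them MRPL34 (1.45-fold) and MRPL35 (1.39-fold), and 1 higher, MRPL17 (23 and 1 adjusted over the list alone). Its median log2 change was -0.13 (list adjusted p = 4.58e-06, and adjusted p = 0.268 with an estimated correlation). The same arm had the ACTB difference higher by 0.35.

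In the list of PGC1 family and mitochondrial transcription genes, members went both ways. TFAM, which packages mitochondrial DNA and helps start its transcription, was 2.02-fold lower (2088 to 1035, adjusted p = 3.97e-06). The nuclear receptor ESRRA (log2 change -0.70) and the mitochondrial helicase TWNK (-0.39) also fell. NRIP1, a corepressor of nuclear receptors, rose 1.82-fold, and PPARG (0.97) and TFB1M (0.32) rose too. With 3 higher and 3 lower of 21 (3 and 4 adjusted over the list alone), the median was -0.08 and the list did not pass (adjusted p = 0.436); fry, which tests whether the genes move on balance in 1 direction, gave an adjusted p of 0.01. In oxidant defence, 9 of 25 fell and 3 rose (9 and 5 adjusted over the list alone): the glutaredoxin GLRX5 was 1.71-fold and the mitochondrial thioredoxin TXN2 1.49-fold lower, heme oxygenase HMOX1 fell by 1.40 on the log2 scale, and GLRX, GPX7 and UCP2 were the 3 that rose, of which UCP2 was also lower in shGFP than in shScr (adjusted p = 0.0113). That list's median was -0.05 and it did not pass (adjusted p = 0.182; fry adjusted p = 0.00132). Glycolysis had 3 genes higher and 3 lower of 21 (3 and 3 adjusted over the list alone), with glucose transporter SLC2A1 1.39-fold, PFKFB3 and ALDOC higher and enolase ENO2 1.99-fold, PFKM and GPI lower (median 0.02, list adjusted p = 0.702). The ACTB difference was 0.35 higher in the same arm.

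Genes of the hypoxia response were higher, with 13 of 18 up and 2 down (14 and 2 adjusted over the list alone). The iron and stress responsive NDRG1 rose 2.17-fold (893 to 1925, adjusted p = 1.86e-05) and the collagen prolyl hydroxylase P4HA2 1.92-fold; the angiogenic factor VEGFA (log2 change 0.97) and ANGPTL4 (1.12) rose too. The 2 that fell were EGLN1, an oxygen-dependent hydroxylase that marks HIF for destruction, and MXI1, an antagonist of MYC; EGLN1 was also higher in shGFP than in shScr (adjusted p = 0.0234). The list median was 0.50 (list adjusted p = 4.56e-06, and adjusted p = 0.225 with an estimated correlation), and between the controls it was 0.28 higher in shGFP. The ACTB difference was 0.35 higher in the knockdown arm.

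Genes of the melanocyte lineage were lower, with 8 of 23 down and 3 up (11 and 3 adjusted over the list alone). The protease gene CAPN3 was 2.55-fold lower (5619 to 2207, adjusted p = 1.61e-06) and RAB38, needed for the transport of pigment enzymes to melanosomes, 1.54-fold lower. The lineage transcription factor MITF (log2 change -0.59), the melanosome protein PMEL (-1.31) and the pigment enzyme TYRP1 (-1.09) fell, while SOX10, MC1R and BCL2A1 were the 3 that rose. TYRP1 was higher in shGFP than in shScr by a log2 difference of 1.35 (adjusted p = 0.00110), more than its change with the PGC1α hairpins. The list median was -0.24 (list adjusted p = 0.00331, and adjusted p = 0.268 with an estimated correlation), and without shGFP the list did not pass (adjusted p = 0.0511, in a range of 7.85e-05 to 0.0511 over 17 alternatives with the preset correlation). The ACTB difference was 0.35 higher in the knockdown arm.

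In the list of invasive melanoma, integrin and extracellular matrix genes, 18 of 46 rose and 4 fell (23 and 4 adjusted over the list alone). The integrin subunit ITGB5 rose 2.37-fold (1668 to 3962, adjusted p = 2.14e-06; the lowest of its 4 probe sets has a log2 change of 0.55) and the matrix protein TGFBI 2.32-fold (2842 to 6599.6, adjusted p = 1.61e-06). Integrin subunits ITGA5 (log2 change 1.40), ITGA3 (1.12) and ITGB3 (1.02), the receptor kinase AXL (1.19) and the mesenchymal transcription factor ZEB1 (1.19) rose too. The 4 that fell were ID1, ID2 and ID3, which inhibit basic helix-loop-helix factors, and TAGLN, an actin-binding protein of contractile cells. ITGA3, AXL, ZEB1 and TAGLN also passed the test between the controls, all 4 lower in shGFP, with adjusted p from 0.00178 for ZEB1 to 0.0312 for TAGLN. The list median was 0.24 (list adjusted p = 4.58e-06, and adjusted p = 0.138 with an estimated correlation). The ACTB difference was 0.35 higher in the same arm.

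Transcriptional output of the MAPK pathway was higher, with 11 of 18 genes up and 1 down (12 and 2 adjusted over the list alone). The immediate early transcription factor EGR1 rose 2.04-fold, and SPRY4 and DUSP6, feedback inhibitors of the pathway, rose by log2 changes of 0.91 and 0.47; the 1 that fell was MYC, a growth-promoting transcription factor, 1.77-fold. Between the controls, EGR1 was lower (adjusted p = 0.0171) and SPRY4 higher in shGFP (adjusted p = 0.0301). The median was 0.30 (list adjusted p = 1.83e-05, and adjusted p = 0.0613 with an estimated correlation). Among inflammatory and NF-kB targets, 8 of 22 rose and 2 fell (9 and 2 adjusted over the list alone): LIF, a cytokine, rose 2.85-fold (1199 to 3410, adjusted p = 3.98e-07), CXCL8 and PTGS2 rose by log2 changes of 1.56 and 1.67, and IL24 and TNFAIP3 fell, both also higher in shGFP than in shScr (adjusted p = 0.00625 and 0.00448). The median was 0.07, though 0.58 without the 40% of genes lowest in mean signal, and the mean 0.35 (list adjusted p = 0.0127, and adjusted p = 0.212 with an estimated correlation), and without shGFP the list did not pass (adjusted p = 0.108, in a range of 0.00442 to 0.108 over 17 alternatives with the preset correlation). The ACTB difference was 0.35 higher in the same arm.

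The other lists did not pass. Of 41 cell cycle genes, 4 rose (BUB1B, TOP2A, TPX2 and NUSAP1) and 8 fell (6 and 8 adjusted over the list alone), among them the phosphatase CDC25A, 1.75-fold, and cyclin CCNE1, 1.22-fold; the median was 0.03, the mean -0.01 and the tested direction lower (adjusted p = 0.886). Of 19 p53 targets, 6 rose, with the death receptor FAS 1.56-fold and SESN1 1.30-fold, and MDM2 and GDF15, 2 in all, fell (6 and 2 adjusted over the list alone; median 0.05, adjusted p = 0.230). That list passed with fry (adjusted p = 0.0336) and with the mean of all probe sets of a gene (adjusted p = 0.05, just under the threshold, in a range of 0.05 to 0.361 over 17 alternatives). Of 30 interferon response genes, 3 rose (ISG15, IFIT5 and IFI35) and 5 fell (3 and 6 adjusted over the list alone), with the antiviral enzyme OAS3 1.34-fold and MX2 1.19-fold lower; the median was 0.01, the mean -0.01 and the tested direction lower (adjusted p = 0.757). For ATF4 and the unfolded protein response, 4 of 25 rose and 4 fell (5 and 6 adjusted over the list alone), among the latter the amino acid transporter subunits SLC7A11 (1.41-fold) and SLC3A2 (1.40-fold), with a median of 0.04 (adjusted p = 0.757). The ACTB difference was 0.35 higher in the same arm.

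In cholesterol synthesis, INSIG1, which restrains the pathway, rose 1.38-fold and the sterol isomerase EBP fell 1.13-fold (adjusted p = 0.0379), out of 17 genes (1 higher and 0 lower adjusted over the list alone; median 0.04, list adjusted p = 0.757). Of 8 RNA interference genes, DICER1 fell 1.64-fold, though its 6 probe sets ranged in log2 change from -0.76 to 0.23, and AGO3 rose 1.42-fold (2 higher and 1 lower adjusted over the list alone; median 0.07, list adjusted p = 0.702). Markers of other cell types were few among the calls. Of 13 epithelial markers, the splicing factor ESRP1 fell 2.82-fold and the keratin KRT18 rose 1.28-fold (1 and 1 adjusted over the list alone), with a median of 0.01, a mean of -0.08 and a tested direction of higher (adjusted p = 0.940). Of 12 fibroblast markers, PDGFRB rose 1.44-fold and 0 fell (1 and 0 adjusted over the list alone; median 0.05, adjusted p = 0.757). Of 10 blood markers, CORO1A rose 1.35-fold and 0 fell (0 and 0 adjusted over the list alone; median 0.02, adjusted p = 0.747). These genes, too, were measured in arms whose ACTB differences were 0.35 apart. With that difference as a covariate, INSIG1, EBP, DICER1, AGO3, KRT18, PDGFRB and CORO1A lost their calls with limma, and ESRP1 kept its call. The log2 change of AGO3 went from 0.51 to 0.31 (adjusted p = 0.491) and that of DICER1 from -0.71 to -0.69 (adjusted p = 0.0626).

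The calls of EBP, KRT18 and CORO1A each depended on single arrays. EBP lost its call without shGFP replicate 2 (adjusted p = 0.0932), shScr replicate 2 (0.0938), hairpin 65 replicate 1 (0.0638) or 2 (0.0557), or hairpin 66 replicate 1 (0.0964) or 2 (0.0754), in a range of 0.0196 to 0.406 over 14 alternatives. KRT18 lost it without shGFP replicate 2 (0.0527) or hairpin 66 replicate 2 (0.0559), in a range of 0.00194 to 0.339. CORO1A lost it without shGFP replicate 1 (0.0526) or 2 (0.0722), hairpin 65 replicate 1 (0.068), or hairpin 66 replicate 1 (0.0748) or 2 (0.0602), in a range of 0.00139 to 0.597. KRT18, CORO1A, AGO3, ESRP1 and CDC25A also differed between the control hairpins, with adjusted p from 0.0121 for AGO3 to 0.0405 for KRT18.

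**Figure D2:**
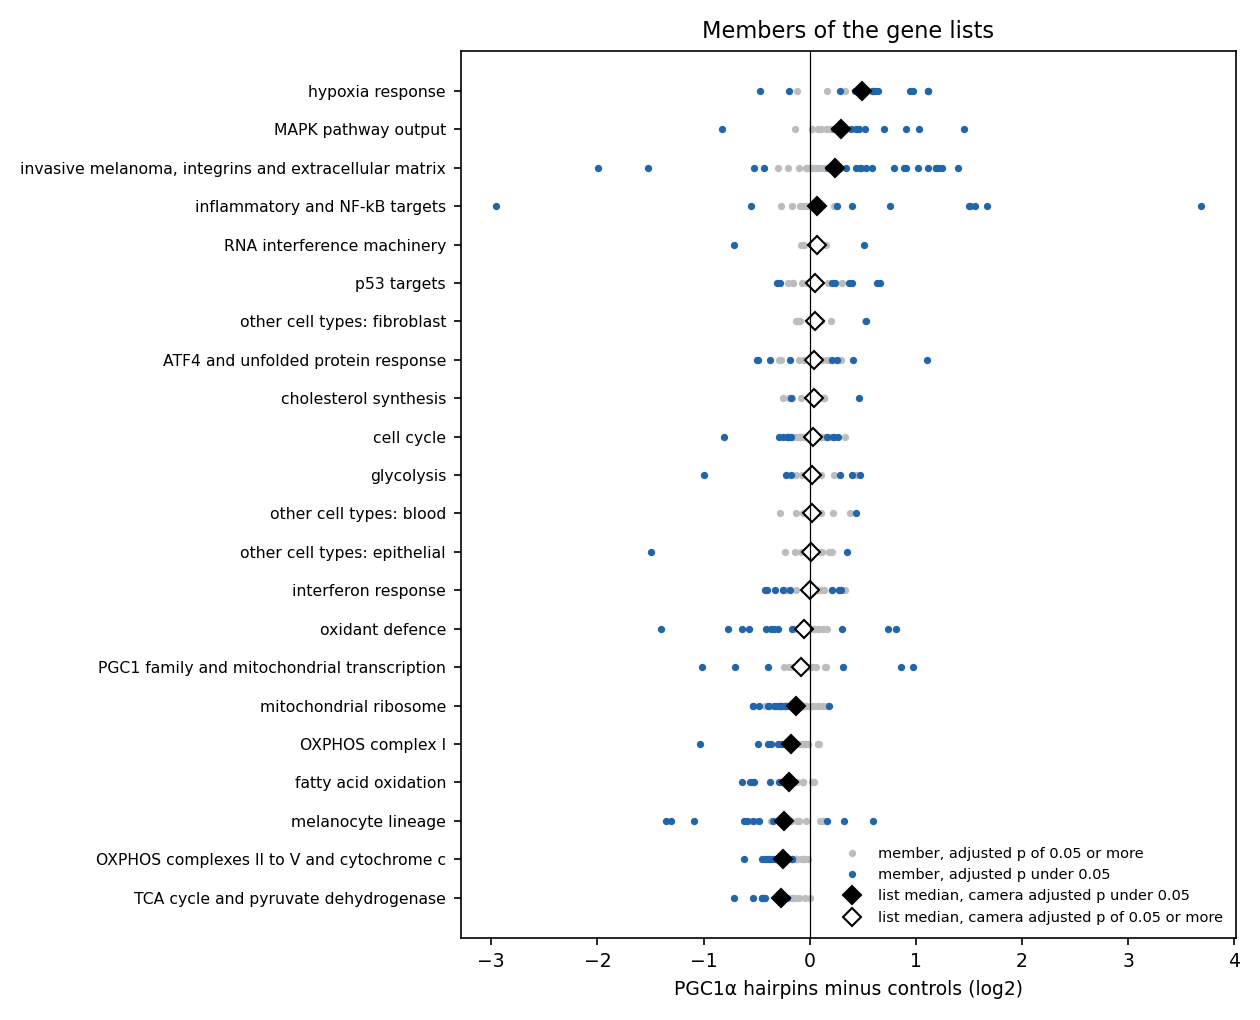
Each point is 1 measured member of a list, placed by its log2 change with the PGC1α hairpins against the controls, and diamonds mark list medians. The list of TCA cycle and pyruvate dehydrogenase genes has the lowest median, -0.27, and the list of hypoxia response genes the highest, 0.50; 10 of 22 lists pass with the preset correlation and 0 with an estimated one.

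Each hairpin was then compared with the controls alone. CEMIP, IL11, INHBA and CHRDL1 had the largest rises, and IL24, GALNT3, DKK1 and PPARGC1A the largest falls, among the genes called with both hairpins. IL24 fell by 2.92 on the log2 scale with hairpin 65 and by 2.99 with hairpin 66, and CEMIP rose by 4.50 and 4.64. Hairpin 65 raised 1556 and lowered 1248 genes, 2804 in all, and hairpin 66 raised 1340 and lowered 1308, 2648 in all. Of the OXPHOS genes of complexes II to V with cytochrome c, 22 fell with hairpin 65 and 23 with hairpin 66, and 14 and 13 genes of the hypoxia response rose.

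Both hairpins raised 1170 genes and lowered 968, 2138 in all, where independent lists would share 174 and 136. The lists are not independent, since both use the same controls, and a gene apart in shGFP alone can be called with both hairpins. SLAMF1 was called as lower with both, at signals of 19.9 and 22.0, against 58.0 with shGFP and 20.3 with shScr. Their log2 changes correlated across genes with r = 0.92, against 0.34 in simulated unchanged groups that shared controls; genes are not independent replicates. With a different control for each hairpin, r was 0.70 and 0.72, and 1291 and 1283 genes were shared. DRICH1 and NRG1 were the 2 genes called in opposite directions, with log2 changes of 0.21 and 0.20 for hairpin 65 and -0.24 and -0.22 for hairpin 66. The hairpin 65 count was 1798 without hairpin 65 replicate 2, 1601 without probe sets of suffix s_at or x_at and 581 at 1.5-fold or more. The hairpin 66 count was 1742 without hairpin 66 replicate 1, and 1549 and 570 in the latter settings, where the shared count was 1217 and 481.

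**Figure D3:**
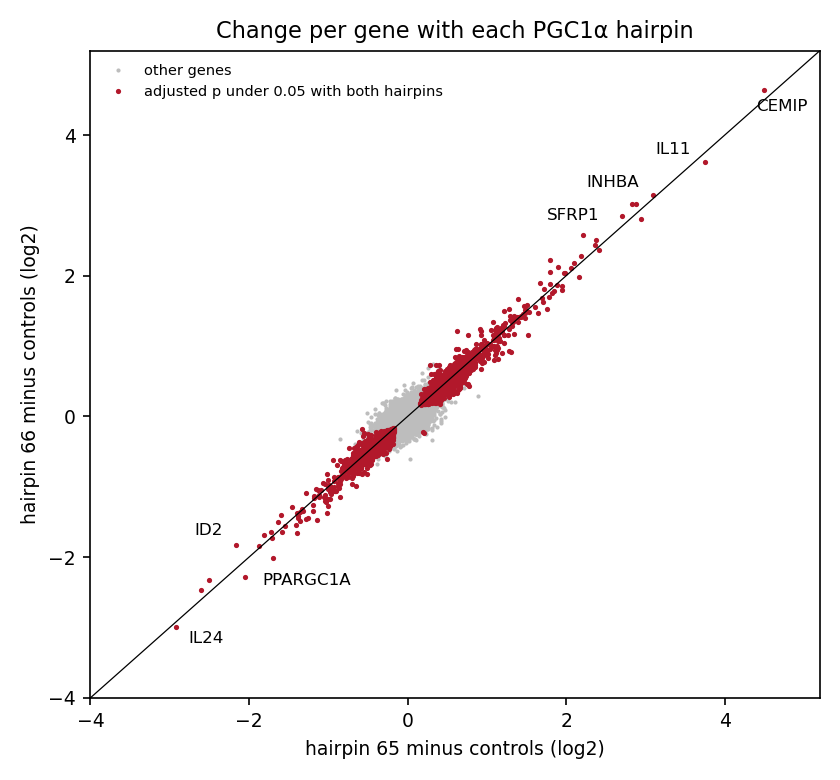
Each point is 1 gene, placed by its log2 change with hairpin 65 (horizontal) and hairpin 66 (vertical) against the controls, and the line marks equal changes. The red points passed with both hairpins, 2138 with the same sign and 2 with opposite signs, and the correlation across genes is 0.92.

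The direct comparison of hairpin 65 with hairpin 66 asked which changes were specific to 1 hairpin. PPARGC1A itself was 0.24 higher on the log2 scale with hairpin 65 (SE 0.07, limma unadjusted p = 0.0147, adjusted p = 0.593). The smallest p belonged to the deubiquitinase USP2, lower with hairpin 65 by a log2 change of -0.39, followed by DRICH1 (0.45), the prostaglandin D synthase PTGDS (0.42) and the growth factor NRG1 (0.42), each at an adjusted p of 0.581. limma called 0 of 11963 genes between these hairpins, with 849 at an unadjusted p under 0.05. Over all genes, the SD of the log2 differences was 0.12.

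The comparison of shGFP with shScr gives the background between control hairpins, and the genes named here pass it. DKK1 had a signal of 364 ± 26.0 with shGFP and 45.3 ± 4.18 with shScr (SD, n = 2 in each group), 8.05-fold higher in shGFP (adjusted p = 2.11e-04). SLAMF1, a receptor of immune cells, was 2.87-fold and the anion exchanger SLC26A4 2.84-fold higher in shGFP. CEMIP was 3.98-fold lower in shGFP (94.1 against 374, adjusted p = 6.19e-05), as were the natriuretic peptide NPPC (2.75-fold), the thioredoxin-binding protein TXNIP (2.72-fold) and TMEM158 (2.68-fold). CEMIP, NPPC and TMEM158 were higher still with the PGC1α hairpins, NPPC 4.24-fold and TMEM158 4.72-fold above the mean of the controls.

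limma called 939 genes between shGFP and shScr, 526 higher and 413 lower in shGFP, or 7.85% of those tested, and the SD of the log2 differences was 0.22. In the list of invasive melanoma genes, 10 of 46 members were higher and 6 lower in shGFP, in the hypoxia list 7 and 1 of 18, in the melanocyte list 6 and 0 of 23, and in the 2 OXPHOS lists together 1 and 1. The mean ACTB difference was 2.15 with shGFP and 2.22 with shScr. The count fell to 412 without shGFP replicate 1, 417 without shGFP replicate 2, 432 without shScr replicate 1 and 374 without shScr replicate 2, where the lone array is assumed to vary like the other groups. It was 1535 without the 40% of genes lowest in mean signal, 1705 with a trend and robust variance, 555 without probe sets of suffix s_at or x_at, and 274 at 1.5-fold or more.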

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

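In this part, the tests of crossed labels, of noise, of a shared hairpin line, of mixed RNA, of repeat arrays against the ACTB difference and of shGFP standing apart were chosen only after the result was seen, as was the ACTB covariate as a setting.

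In 2 of 130 groups of 4 arrays tested, 1 array stood apart from the other 3 by more than the critical gap, where chance alone gives 6.5. GALNT3 in hairpin 66 replicate 2 was apart by 0.914 of the range of the knockdown arrays. SESN1 in hairpin 66 replicate 2 was apart by 0.831 of that range. Of 3151 probe sets with several gene symbols or none, which the gene-level comparisons left out, 286 changed with the PGC1α hairpins, 156 higher and 130 lower.

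The knockdown effect differed by the control it was measured against for 939 genes, those apart between shGFP and shScr. Across genes, the shift of shScr from shGFP correlated with the shift of the knockdown from the controls (r = 0.33, against -0.0277 to 0.0301 in 200 simulations of unchanged groups). Both shifts use the same controls, so shGFP standing apart alone could give this r. With the knockdown set against shScr, on separate shScr arrays, r was 0.0443, against a simulated range of -0.0266 to 0.0303. The simulations drew each gene independently, so both ranges are too narrow for genes that vary together. Whether a remainder is left cannot be told. Knockdown RNA or cells mixed into the shScr samples are argued against only at the share that the slope of 0.25 between these shifts would need. PPARGC1A was 0.0249 higher in shScr (SE 0.07), where that slope predicts a log2 change of -0.53. The slope uses the same controls in both shifts, and a smaller share, with a fall of PPARGC1A within its spread, is not excluded. RNA quality stays undecided, and the ACTB covariate, which left r at 0.364, is weak evidence. Between repeat arrays of a hairpin the position on the knockdown axis moved with the ACTB difference by a slope of 0.0449 (SE 0.0174), where 3.56 would be needed. That needed slope rests on a small gap between the controls (mean ACTB difference 2.15 with shGFP and 2.22 with shScr). The slope argues against RNA quality as the whole cause only if repeat arrays come from separate cultures, which the labels do not say. Also open are an effect of a control hairpin or a difference between the cultures, which no test here separates, and the deposited normalization. Cyclic loess left r at 0.333 but moved the shifts by 0.00500 at the median against a standard error of 0.0819.

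The fall of the OXPHOS lists, a median log2 change of -0.21 over 64 genes, was set against technical explanations. A fall of brightly hybridised probe sets as a class is argued against, because 10000 random lists matched in signal had medians with a lower 2.5% bound of -0.0158, and 0 reached -0.21. Of the RNA quality probe sets, those of ACTB differed between the arms. Those of GAPDH did not pass (0.17 in the controls and 0.18 in the knockdown, exact permutation p = 0.571). With the ACTB difference as a covariate 105% of the median was kept and 5 of 38 called members still passed. This is weak evidence, since the covariate follows the arms (variance inflation 2.82) and 0 genes had a slope on it that passed. Within hairpins the OXPHOS median moved with the ACTB difference by a slope of 0.0813 (SE 0.0486), where -0.601 would be needed. In single hairpins the slope ran from 0.00364 to 0.339. These slopes argue against RNA quality as the whole cause only if repeat arrays come from separate cultures, which the labels do not say. A part in single genes stays open in any case. A lower expression of these genes with less PGC1α may be the source, a hypothesis that no test here separates from other effects of the hairpins.

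Hairpins 65 and 66 gave 0 genes apart with limma (849 at an unadjusted p under 0.05), while the control hairpins gave 939. The better of the other 2 pairings of the 4 knockdown arrays also gave 0, so crossed labels did not hide genes that another pairing would call. Where no pairing gives a called gene, whether labels were crossed cannot be told. More noise in the knockdown arrays, hiding differences as large as those between the controls, is argued against. The SD over genes of the log2 changes between the hairpins was 0.118, below the 0.216 between the controls. The 95% interval of the difference was 0.0913 to 0.105 over resampled genes of these arrays, so it holds no spread between arrays. The 4 knockdown arrays could still come from 1 hairpin line. The SD between the hairpins was 0.959 times (0.939 to 0.979 over resampled genes) the larger SD of the other pairings. It lay between the SDs of those 2 pairings, 0.110 and 0.123, which gave 632 and 1021 genes at a limma unadjusted p under 0.05. PPARGC1A differed between the hairpins at a limma unadjusted p of 0.0147. A common response to the loss of PGC1α would give the same values, and the effects of independent hairpins cannot be separated from those of 1 line here.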

How the results depend on the processing

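In this part, the ACTB covariate, the estimated correlation in the 4-group fit, the crossed replicate block and the other pairings were chosen only after the result was seen. PPARGC1A has 1 probe set, so a comparison of its probe sets was not run. Its log2 change stayed between -2.23 and -2.12 and past the threshold in all 11 alternatives run. Of 880 values of the other genes the rule takes, 847 kept their direction and call, 33 lost the call and 0 reversed. With the ACTB covariate 12 genes lost it: DKK1, NDUFA3, CCNE1, MX2, SLC7A11, INSIG1, EBP, DICER1, AGO3, KRT18, PDGFRB and CORO1A. The log2 change kept its size in NDUFA3 (-0.484 without, -0.486 with the covariate) and shrank in AGO3 (0.508 without, 0.308 with it). In another setting 4 genes lost it (DKK1, EBP, KRT18 and CORO1A), all among the 12. Of 440 values of list medians, 393 kept direction and call, 22 lost the call, 4 gained it and 21 changed sign, in 6 lists near 0 that pass in none of these settings; the cause was not tested. Those were cell cycle (-0.0220 with the mean of all probe sets, -0.0130 without hairpin 66, -0.0385 without shGFP, -0.0212 with the ACTB covariate, -0.0199 to 0.0675 without 1 array), interferon (-0.0210 without hairpin 65, -0.0482 with the covariate, -0.0141 to 0.0215 without 1 array), cholesterol synthesis (-0.0228 without shScr, -0.00478 with the covariate), epithelial (-0.00390 with the mean of all probe sets, -0.0552 without shScr, -0.0183 to 0.0682 without 1 array), fibroblast (-0.0555 without shScr, -0.00451 to 0.124 without 1 array) and blood markers (-0.0146 to 0.0679 without 1 array). With an estimated correlation 0 of 22 lists passed in the 2-group fit and 0 in the 4-group fit, against 10 with the preset one and 13 with fry.

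For PGC1α hairpins against controls, hairpin 65, hairpin 66, shGFP against shScr, and genes shared by both hairpins, the counts without probe sets of suffix s_at or x_at were 1601, 1601, 1549, 555 and 1217, with fewer genes tested. At 1.5-fold or more they were 552, 581, 570, 274 and 481. The main count was 1387 without hairpin 65, 1467 without hairpin 66 and 878 with averaged arrays, all with fewer values, 3989 with all probe sets tested singly, where more are tested, and 529 with the ACTB covariate, where the log2 changes of called genes were 0.956 times as large at the median and their standard errors grew 1.77-fold. shGFP against shScr gave 1535 without the 40% of genes lowest in signal and 1705 with a trend and robust variance; the cause was not tested. Without 1 array, counts ranged from 2104 to 2489 (main), 1798 to 2713 (hairpin 65, lowest without its replicate 2), 1742 to 2572 (hairpin 66, lowest without its replicate 1), 1516 to 1669 (shared), 374 to 847 (shGFP against shScr, 412 and 417 without shGFP replicate 1 or 2, 432 and 374 without shScr replicate 1 or 2) and 0 to 0 (hairpin 65 against 66), and the lists from 10 to 10. Of the 2659 main calls, cyclic loess, which moved values little, changed the sign of 0 and the mean of all probe sets that of 10; without probe sets of suffix s_at or x_at, 55 of the 1799 still measured changed sign and 1513 kept their call, as another probe set then stands for the gene. Without detection calls, how far signal over background limits low genes is unknown.

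With the replicate number as a block, the counts were 2437 (main), 2581, 2423, 782 (shGFP against shScr), 1960 (shared) and 0 (hairpin 65 against 66), 10 lists passed, PPARGC1A changed by -2.16 and DKK1 lost its call (adjusted p = 0.0510, in a range of 1.03e-05 to 0.563 over 14 alternatives). The numbers do not pair the arrays, as deviations of arrays with the same number correlated between -0.107 and 0.0426 over 6 pairs of groups. A crossed block gave 0 genes between hairpins 65 and 66.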

Other observations

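In this part, all 6 lists were written after the first results, single members of some (PEX19, CAT, GLRX5, ID1, ID2 and ID3 among them) had been seen by then, and the tests of the lysosome and BMP response lists were chosen only after the result was seen.

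Genes for protein import into mitochondria were lower with the PGC1α hairpins. Of 27 measured members, 11 fell and 1 rose (14 and 1 adjusted over the list alone), with a median log2 change of -0.14 (list adjusted p = 8.45e-05, and adjusted p = 0.201 with an estimated correlation). TIMM44, which tethers the import motor to the inner membrane, was 1.42-fold lower, the translocase subunit TIMM17A 1.36-fold, the insertase OXA1L 1.31-fold and the outer membrane pore TOMM40 1.26-fold; TOMM34, a cytosolic cochaperone, rose 1.28-fold. Genes of heme and iron-sulphur cluster synthesis had 6 members lower and 2 higher of 21 (adjusted p = 0.164), with the first heme enzyme ALAS1 1.26-fold lower and the mitochondrial iron importer SLC25A37 1.63-fold higher. Among 26 peroxisome genes, 5 fell and 2 rose (adjusted p = 0.321), with the membrane protein import factor PEX19 2.23-fold lower (adjusted p = 1.11e-06). Of 43 cytosolic ribosome genes, 0 changed with limma (median 0.00, list adjusted p = 0.948). The ACTB 3′ over 5′ difference was 0.35 higher in the same arm.

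Of 37 lysosome genes, 8 fell and 5 rose (list adjusted p = 0.416): the protease CTSL was 2.57-fold lower (adjusted p = 4.57e-07) and the saposin precursor PSAP 1.67-fold lower, while the sulfatase IDS was 1.81-fold higher. Of 13 genes of the BMP response, 5 fell and 2 rose (list adjusted p = 0.0897, and adjusted p = 0.201 with an estimated correlation). ID3 was 2.88-fold, ID2 3.99-fold, MSX1 1.49-fold and ID1 1.35-fold lower, and the pathway inhibitor SMAD7 rose 1.54-fold. BAMBI fell and ID4 rose.

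Other splits of the 8 arrays into 4 and 4 were counted. The real split gave 2659 changed genes and the highest of the other 34 gave 0. Thus 1 of 35 splits reached the count, the smallest share possible. Every other split mixes knockdown and control arrays, which adds the arm difference to the residual spread. The share counts against chance only if the 8 arrays are independent. They come in 2 per hairpin, and 939 genes differed between the control hairpins. With hairpins kept whole there are 3 splits, too few for a share under 0.05, so chance is not excluded. Of these 3, the real one gave 2659 genes and the highest other 0. For the gene lists, 2 of 35 splits gave 10 lists, the highest other being 10, so chance cannot be excluded for the number of lists. The other split with 10 lists set shGFP replicate 1, hairpin 65 replicate 1 and both hairpin 66 arrays against the rest, so it kept 3 knockdown arrays together. Splits that keep 3 arrays of an arm together gave 5 to 10 lists, and those with 2 arrays of each arm on a side gave 0 or 1. A split with 3 together still holds part of the arm difference, so the share of splits is a poor measure of chance for lists.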
